A study of Oryza sativa with 6 samples.

How the data were processed

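Young panicles of rice (Oryza sativa) carrying the lemmata mutation and of wild type were profiled on one-colour Affymetrix rice genome arrays, with 3 arrays per group. Per the labels, panicles of 2 to 10 mm were collected from field-grown plants, and biotin-labelled cRNA was made from 5 µg of total RNA. The labels call the mutant an indica rice and the wild type a cross of an indica with a japonica cultivar, so the groups may differ in background as well as at the mutated gene. The labels do not say whether replicates came from separate plants, so p-values measure the spread between these samples, which may be partly technical.

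The deposited intensity values are the authors' MAS5 signal on a linear scale, made with GCOS and MAS5 per the submitters' processing notes, with versions not given in the sources used here. On every array the mean signal after leaving out the lowest and highest 2% of values lay between 499.9 and 500, which shows a per-array scaling by the authors. Such a scaling removes any change that affects most transcripts alike. Detection calls and probe-level data were not used here, and the number of arrays limits the precision.

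The 123 control probe sets were left out of the tests, which left 57258 probe sets. Values were used as log2(signal + 3), where 3 is the rounded 10th percentile of all signals, and all log2 changes are on that scale, which understates the change of dim probe sets. Probe sets whose mean over the 6 arrays was above the 40th percentile, a signal of about 23.2, were tested, which gave 34355. Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend, without a replicate block, and with Benjamini-Hochberg adjustment at 0.05. On simulated data for this comparison, with 200 of 34355 probe sets changed, the fit recovered 26% of 2-fold changes, 62% of 4-fold, 84% of 8-fold and 92% of 16-fold changes, and 6.4% of its calls were false. The simulated noise was normal and independent between probe sets and arrays. It held no effect of replicate number and no outlying array, so the shares for the real data may differ.

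Names came from the array annotation, updated through the gene table of the rice assembly ASM3414082v1. Of the probe sets, 22436 had 1 gene symbol, 95 had several and 34727 had none, and those with several or none are called unnamed here. No coordinates are given, since the values name no build. The table was used for names and for which genes neighbour each other.

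Gene lists were tested with camera at a preset correlation of 0.01 on the brightest tested probe set of each gene, with fry and with camera at an estimated correlation beside it. Of 26 lists fixed before the data were examined, 23 had at least 5 tested genes. The lists of resistance genes, class III peroxidases and transposable elements had fewer and were not tested. The lists of developmental genes were fixed by name. The other lists had been fixed as gene descriptions, which the tables used here do not hold, so they were rewritten as patterns of gene names after a first fit had been seen and before any list was tested. They are smaller than planned, and organelle genes were left out of them. A list of 28 tested water stress and abscisic acid genes was added after the data had been seen.

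The genes named were set by a rule fixed before the data were examined. It takes the 10 largest changes in each direction among passing probe sets that separate the groups fully and pair with 1 gene, or, in a direction where none passes, the 5 of smallest p. It adds up to 4 passing members of each list, or its brightest member where none passes, and MADS1, MADS6, MADS14, MADS15, MADS34, DL, G1, OSH1, FZP and LAX1 in any case. For G1 no named probe set was matched, and it is not analysed here. Other features are named as chosen after their values were seen.

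A background level was added after the data had been seen: on each array, the 95th percentile of 33 control probe sets with no rice target, which lay between 24.8 and 56.9. Where all 3 arrays of a group were at or below it, the fold is given as a lower bound against that level.

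Replicate numbers are shared by the groups in the labels. Deviations from the group means correlated at 0.14, 0.23 and 0.3 between the mutant and wild-type arrays of the same number, each above 0.1, so the numbers pair the samples. The pairing comes from the values, since no label says what a number marks. The signal of the spiked-in control dap also followed the number. In mutant and wild type it was 3568 and 3677 for number 1, 4025 and 4878 for number 2, and 8686 and 7640 for number 3. The main fit does not use the pairing, so its p-values also hold the spread between replicate numbers. Control genes were compared by their 3' minus 5' log2 signal with exact two-sided permutation tests, for which the smallest p with 3 against 3 is 0.1. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 11, no filter and a filter at the 60th percentile. Further ones were other variance models, a replicate block, leaving out each array, and leaving out probe sets whose names end in _x_at, _s_at or _a_at. The last were a plain test with pooled variance, the mean of a gene's probe sets and an estimated correlation. Leaving out both replicate 3 arrays was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.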

Results

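Transcript levels were measured in young rice panicles of the lemmata mutant and of wild type, on 3 arrays per group. Median signals lay between 41.7 and 56.7, and 48.2% to 61.7% of the probe sets on an array were above the level of control probe sets with no rice target. Correlations of log2 signal over tested probe sets were 0.95 to 0.969 within groups and 0.947 to 0.975 between groups, and no 2 arrays were identical. Wild-type replicate 1 stood apart on the first principal component, which held 29.7% of the variance, with a score of -99.8 against -1.8 to 36.6 for the other arrays. The 3' minus 5' log2 signal of the control genes followed the replicate number. For GAPDH it was 3.04 ± 1.21 (SD, n = 3) in the mutant and 2.93 ± 1.16 (SD, n = 3) in wild type (exact two-sided permutation p = 0.8, adjusted 0.9 over 3 control genes). For actin the difference between groups was 0.03 (exact permutation p = 0.9), and for cyclophilin it was 0.07 (exact permutation p = 0.8). These tests do not use the pairing by replicate number. Within pairs, mutant minus wild type ran from -0.06 to 0.33 for GAPDH, -0.2 to 0.25 for actin and -0.07 to 0.23 for cyclophilin.

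The comparison of mutant with wild type asks which transcripts differ in the developing panicle between these groups, which may also differ in background. A lower signal may therefore also come from a sequence difference under the probes, which was not tested. Of the 6 probe sets that passed, 3 were of MADS-box genes that specify floral organs. MADS7 and MADS8, class E genes needed for the inner organs of the floret, fell by 2.65 ± 0.15 (SE) and by 2.78 ± 0.16 (SE) on the log2 scale. MADS58, a class C gene of stamens, carpel and meristem determinacy, fell by 4.08 ± 0.27 (SE). The mean signal of MADS7 was 670 ± 67.9 (SD, n = 3) in the mutant and 4220 ± 249 (SD, n = 3) in wild type. That of MADS8 was 574 ± 74.5 (SD, n = 3) against 3950 ± 427 (SD, n = 3), and that of MADS58 was 50 ± 9.96 (SD, n = 3) against 903 ± 232 (SD, n = 3). MADS58 was at or below background on 2 of the 3 mutant arrays, and with these set to background its log2 change was -4.02.

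Of 34355 probe sets tested, 6 passed an adjusted p of 0.05 in limma, all 6 were lower in the mutant by at least 2-fold, and 0 were higher. At an unadjusted p under 0.05 there were 1526, against 538 to 3478 in the other splits of the 6 arrays into 3 and 3. The groups did not overlap for 9.7% of probe sets, against 10% by chance. The 3 other splits that part all 3 replicate pairs, as the real one does, gave 538, 597 and 753. The real count was above these, so it leaves further differences open, but it singles out no probe set. The 10% by chance takes no account of the pairing. For the 3 MADS-box genes that passed, limma adjusted p was 0.000493 for MADS7 and MADS8 and 0.000644 for MADS58. The others that passed were LOC4330327, LOC4342941 and 1 probe set, unnamed here and chosen after its values were seen. LOC4330327 fell by 4.55 ± 0.28 (SE) on the log2 scale, from a signal of 694 ± 61.2 (SD, n = 3) in wild type to 27.4 ± 8.91 (SD, n = 3) in the mutant (limma adjusted p = 0.000493). It was at or below background on 2 of the 3 mutant arrays, and with these set to background its log2 change was -3.9. In the gene order of ASM3414082v1 it directly neighbours MADS6. The unnamed probe set had signals of 342.3 to 603.2 on the wild-type arrays and 1.1 to 3.3 on the mutant arrays, at or below background there, and was at least 10.99-fold lower (limma adjusted p = 0.000493). LOC4342941 fell by 2.7 ± 0.3 (SE) on the log2 scale (limma adjusted p = 0.0451). Its call was lost on leaving out any 1 array except mutant replicate 3 (limma adjusted p = 0.0958, 0.11, 0.16, 0.213 and 0.256, against 0.0385 without mutant replicate 3), with quantile normalization (0.0537) and without a trend (0.276).

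With the replicate number as a block, 8 probe sets passed, the 6 above and 2 more, all lower in the mutant. These were MADS16, the class B gene of lodicules and stamens, at -2.28 (limma adjusted p = 0.131, and 0.0471 with the block), and another unnamed probe set, chosen after its values were seen, at -3.08 (limma adjusted p = 0.0541, and 0.0471 with the block). Without wild-type replicate 1, 7 passed, of which 5 were among the 6, and MADS16 was one of them (limma adjusted p = 0.0119). With both replicate 3 arrays left out, an alternative added after the data had been seen, 0 passed in limma and 1523 had an unadjusted p under 0.05. The log2 change of MADS7 was then -2.66 (limma adjusted p = 0.0553) and that of MADS58 was -3.92 (limma adjusted p = 0.0873).

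**Figure D1:**
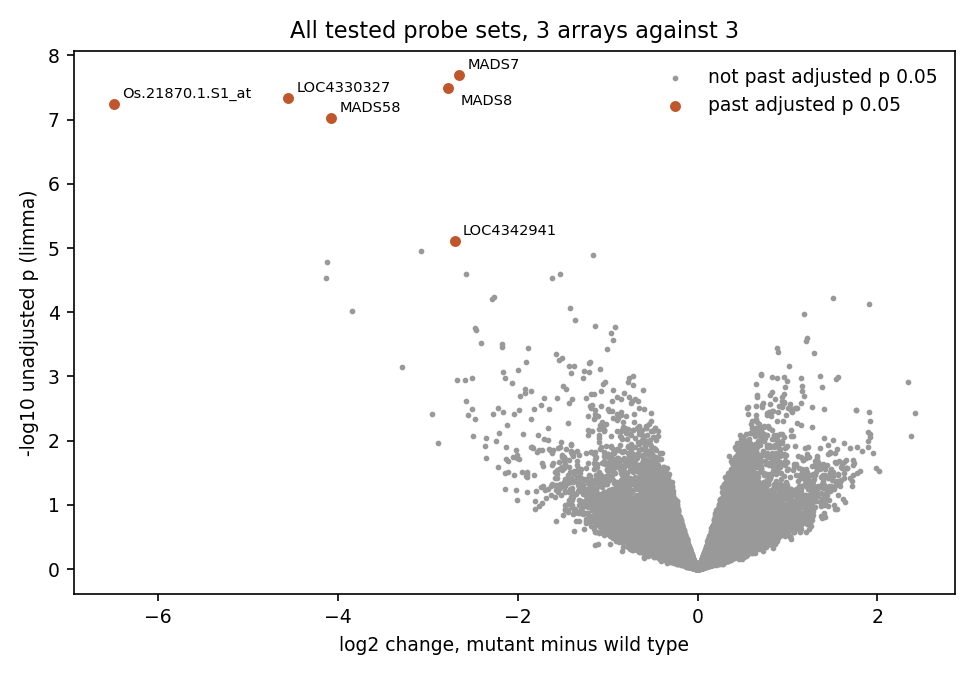
Each point is 1 of 34355 tested probe sets, with the log2 change, mutant minus wild type, on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 6 probe sets past an adjusted p of 0.05 are coloured and named, and all lie on the side of lower signal in the mutant.

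Among the floral organ and spikelet MADS-box genes with DL, 18 genes were tested. Adjusted over all probe sets, 3 fell and 0 rose. Adjusted over the list alone, 7 fell, 4 rose and 7 did not pass. The 7 that fell were MADS7, MADS8, MADS58, MADS16, the class B gene MADS4, the class C gene MADS3 and MADS22, which belongs to the SVP-like genes of meristem identity. MADS4 was at -1.42 ± 0.21 (SE), with an adjusted p of 0.000259 over the list alone. MADS3 was dim, with 16.7 ± 10.9 (SD, n = 3) in the mutant, at or below background, against 107 ± 26.4 (SD, n = 3) in wild type, at least 2.56-fold lower. The 4 that rose were MADS17, at 1.5 ± 0.21 (SE), MADS6, at 0.83 ± 0.19 (SE), the carpel gene DL, at 0.83 ± 0.17 (SE), and MADS1, at 0.49 ± 0.17 (SE). None of these 4 passed over all probe sets, with adjusted p = 0.131 for MADS17, 0.671 for MADS6, 0.556 for DL and 1 for MADS1. The list as a whole was lower (camera adjusted p = 1.98e-05), with a median of -0.37, also with MADS3 at its bound, and a mean of -0.85. The call was lost with an estimated correlation (adjusted p = 0.243). The median was -0.16 without mutant replicate 1, -0.77 without mutant replicate 2 and -0.22 without wild-type replicate 1, and camera at the preset correlation kept the call in each of these fits. Over the list alone 7 fell without any 1 array, and 3 in place of 4 rose without mutant replicate 1, wild-type replicate 2 or wild-type replicate 3. Without probe sets whose names end in _x_at, _s_at or _a_at, 12 genes were tested, of which 4 fell and 3 rose. This setting left out MADS7, MADS3 and MADS17, whose probe sets end in _a_at, and MADS22, whose probe set ends in _s_at. With the filter at the 60th percentile, 16 were tested, of which 6 fell and 4 rose. In fry the list moved one way on balance (adjusted p = 0.01), but not with the block (adjusted p = 0.335), and its genes changed in either direction in both fits (adjusted p = 2.69e-05, and 0.0142 with the block).

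Members with little difference included several expressed at high signal. MADS14, an AP1-like gene, was at -0.1 ± 0.15 (SE) and MADS15 at 0.18 ± 0.19 (SE) on their brightest probe sets. Each has 4 probe sets, which ran from -0.35 to 0.05 for MADS14 and from 0.18 to 0.3 for MADS15. MADS34, a gene of spikelet meristem identity, was at -0.09 ± 0.29 (SE), with an adjusted p of 1 in limma.

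**Figure D2:**
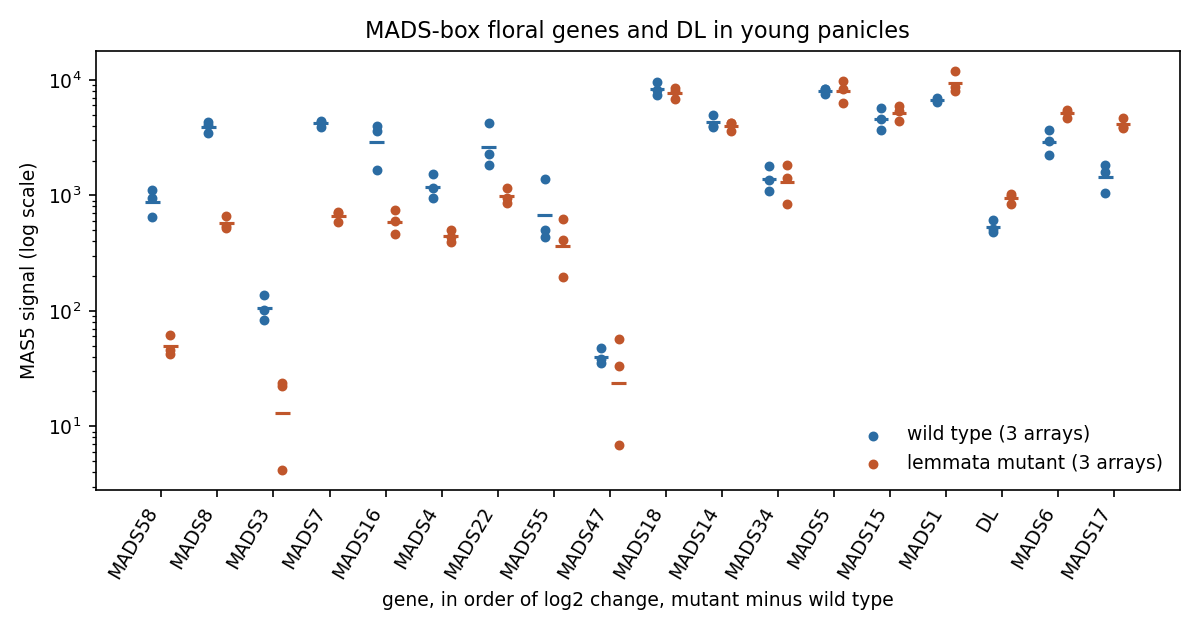
MAS5 signal, on a log axis, of the 18 tested genes of the MADS-box list on the 3 wild-type and the 3 mutant arrays. Points are arrays and bars are group means of log2 signal. MADS58, MADS8 and MADS7 on the left are lower on all 3 mutant arrays, and DL, MADS6 and MADS17 on the right are higher on all 3.

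No probe set passed in the direction of higher signal in the mutant. The 5 with a gene name and the smallest p did not pass. MADS17 led them, followed by LOC4339516 at 1.22 ± 0.21 (SE), LOC4324153 at 0.88 ± 0.16 (SE), LOC4336384 at 0.9 ± 0.17 (SE) and the cell wall invertase gene CIN2 at 1.29 ± 0.24 (SE). Their adjusted p ran from 0.131 to 0.398 in limma.

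Genes of DNA replication were higher in the mutant as a list (camera adjusted p = 1.15e-11, median 0.39 over 29 genes). The call was lost with an estimated correlation (adjusted p = 0.792), and fry gave no call (adjusted p = 0.542, and 0.248 for changes in either direction). Over all probe sets 0 passed, and adjusted over the list alone 8 rose and 0 fell, among them RPA2A at 0.99 ± 0.26 (SE), MCM7 at 0.96 ± 0.29 (SE) and MCM6 at 0.88 ± 0.24 (SE), which were chosen after their values were seen. Wild-type replicate 1, the array that stood apart, was low for this list, with a median deviation of -0.62 from the other arrays against -0.08 and -0.04 for the other wild-type arrays. Without it the list median was 0.26 (camera adjusted p = 4.28e-08), 8 rose over the list alone, and MCM5 was at 0.51 in place of 0.86, RPA2A at 0.7, MCM7 at 0.61 and MCM6 at 0.61. Over the list alone 0 rose without mutant replicate 1, 0 without mutant replicate 2 and 1 without mutant replicate 3. The brightest member, RFC4, was at 0.21 ± 0.15 (SE). Cyclins and B-type cyclin-dependent kinases were higher as a list (camera adjusted p = 0.000765, median 0.25 over 16 genes), with 0 members passing. The call was lost with an estimated correlation (adjusted p = 0.792), and fry gave no call (adjusted p = 0.543, and 0.248 for changes in either direction). CDKB2-1 was at 0.43 ± 0.2 (SE). Without wild-type replicate 1, where this list was also low at -0.36, the median was 0.15 (camera adjusted p = 0.0369). The 5 histone genes, all of the H2B type, had a median of 0.23 (camera adjusted p = 0.0639, and 0.00168 with the block; adjusted p = 0.898 with an estimated correlation), and H2B.6 was at 0.12. Without mutant replicate 1 the histone median was 0.11 (camera adjusted p = 0.508). Meiosis genes had a median of 0.26 over 9 genes (camera adjusted p = 0.0559, and 0.0436 with the block; adjusted p = 0.792 with an estimated correlation), and PAIR2 was at 0.11. Without wild-type replicate 1 the median was 0.14 (camera adjusted p = 0.178). Photosynthesis genes, markers of green tissue, had a median of -0.19 over 5 genes (camera adjusted p = 0.0655, and 0.0399 with the block; adjusted p = 0.792 with an estimated correlation), and OEE3 was at -0.19. The photosynthesis median was -0.1 without wild-type replicate 2 (camera adjusted p = 0.357), -0.31 without wild-type replicate 3 (0.011) and -0.3 without mutant replicate 2 (0.0154). Anther wall and tapetum genes had a median of 0.14 over 7 genes (camera adjusted p = 0.821), and MSP1 was at 0.31.

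The 10 spikelet and panicle meristem regulators did not differ as a list (camera adjusted p = 0.783), with a median of 0.09 and a mean of -0.09. Its genes changed in either direction in fry (adjusted p = 0.00325), but not with the block (adjusted p = 0.151). Adjusted over the list alone 0 passed, and with the block OSH6, OSH71 and RFL rose and LOG and OSH43 fell (each 0.0401 over the list alone with the block), all named after their values were seen. The meristem gene OSH1 was at 0.18 ± 0.12 (SE) on its tested probe set, and SPL14 at -0.1. FZP, which sets floret identity, was at -0.14 ± 0.38 (SE) with a mean signal of 53.2 in the mutant and 56.7 in wild type, and LAX1 was at 0.35 ± 0.25 (SE). Lateral organ polarity genes had a median of -0.04 (camera adjusted p = 0.858) with YAB1 at -0.04. Hull and grain size genes had a median of 0.06 (camera adjusted p = 0.903) with GRF6 at -0.06. Flowering time genes had a median of 0.11 (camera adjusted p = 0.821) with PHYA at -0.09.

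Hormone lists did not differ as lists. Camera adjusted p was 0.821 for auxin, 0.948 for cytokinin, 0.821 for gibberellin, 0.75 for jasmonate and 0.858 for brassinosteroid genes. Their brightest members were ARF23 at 0.06, AHP2 at 0.07, GID1 at -0.42, TIFY3 at 0.19 and BRI1 at 0.05. Adjusted over the list alone, 1 of 28 cytokinin genes passed and was lower, LOGL9 at -1.27 ± 0.26 (SE), chosen after its values were seen. It did not pass with the block (0.0227 over the list alone, and 0.0605 with the block). Cytokinin genes changed in either direction in fry (adjusted p = 0.00224), but not with the block (adjusted p = 0.185). With the block, IAA25, named after its values were seen, was lower at -0.84 (0.0293 over the auxin list alone), and so was GID1 (0.0328 over the gibberellin list alone).

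Cell wall genes (camera adjusted p = 0.75, CESA6 at 0.15), lignin and phenylpropanoid genes (camera adjusted p = 0.903, PAL at -0.21) and cytosolic ribosomal protein genes (camera adjusted p = 0.711, RPS21 at 0.11) did not differ as lists. Nor did heat shock (camera adjusted p = 0.907, HSP81-3 at 0.09), pathogenesis-related (camera adjusted p = 0.186, RBBI3.3 at -0.82), lipid transfer protein (camera adjusted p = 0.118, LTPL1 at -0.29) and seed storage genes (camera adjusted p = 0.886, GLB at 0.24).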

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

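Leaving out both replicate 3 arrays was chosen after seeing the data, and all other alternatives before. The count of 6 probe sets, all lower, stayed between 5 and 8 except in 3 settings. A pseudocount of 11 gave 10, leaving out both replicate 3 arrays gave 0, and a plain test with pooled variance gave 0 after adjustment, with 1584 at an unadjusted p under 0.05 and 254 of at least 2-fold among them. Leaving out 1 array gave 5 to 7. Fewer samples account for part of the loss without the replicate 3 arrays, and otherwise the cause was not tested. With the replicate block 8 passed, and the changes of call are given with the results they concern. No named result that was called changed sign.

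With an estimated correlation the MADS-box list had an adjusted p of 0.243, and the cyclin and DNA replication lists 0.792. The lists below that were not called had 0.792 (meiosis, photosynthesis, lipid transfer proteins), 0.898 (histones, pathogenesis-related genes) and 0.918 (ribosomal proteins, jasmonate) with it. Median centring gave 0.0474 for the meiosis and for the photosynthesis list. The replicate block gave 0.0436 for meiosis, 0.00168 for histones and 0.0399 for photosynthesis, which had 0.0365 without both replicate 3 arrays. Calls appeared without wild-type replicate 1 for histones, ribosomal proteins and jasmonate (0.0343 each), without wild-type replicate 2 for meiosis (0.0318) and jasmonate, without wild-type replicate 3 for meiosis, photosynthesis, pathogenesis-related genes and lipid transfer proteins, without mutant replicate 2 for photosynthesis and pathogenesis-related genes (0.0154 each), and without mutant replicate 3 for histones. Over the 6 fits leaving out 1 array, adjusted p ran from 0.0256 to 0.194 for meiosis, 0.00867 to 0.566 for histones, 0.0343 to 0.896 for ribosomal proteins, 0.011 to 0.357 for photosynthesis, 0.00776 to 0.84 for pathogenesis-related genes, 0.0044 to 0.744 for jasmonate and 0.015 to 0.892 for lipid transfer proteins. The lowest correlation within a group was 0.957 with a pseudocount of 11. Dim probe sets are limited by the background of 24.8 to 56.9.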

Other observations

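The tests of RNA quality and of scaling for the MADS-box genes, the test for LOC4330327, and the test of RNA degradation in wild-type replicate 1 were chosen only after the result was seen. MADS13, a class D gene of the ovule, was too dim to be tested. Its signal was 38.5 to 61.1 on the wild-type arrays, and on replicate 1 the 38.5 was below that array's background of 56.9. On the mutant arrays it was 1.9 to 5.4, at or below background, which gives a bound of only 1.26-fold lower. Without the filter its limma adjusted p was 0.435. MADS2, a class B gene left out of the list because its name matches more than 1 gene in the table, was at 0.09 ± 0.16 (SE), while the other class B genes MADS4 and MADS16 fell when adjusted over the list alone.

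The 6 probe sets called compare with at most 1 in the other splits of the 6 arrays, and 1 of the 10 splits, the real one, gave as many, which is too few splits for a share under 0.05. The 3 other splits that part all 3 pairs gave 0 calls with the block, against 8.

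Over the MADS-box list alone MADS7, MADS8, MADS58, MADS16, MADS4, MADS3 and MADS22 fell in the mutant, while DL rose and MADS2 was at 0.09. Sampling of younger mutant panicles would also lower genes that act later. The 16 tested meiosis and anther genes had a median of 0.19 (95% bootstrap interval 0.06 to 0.31). The 9 meiosis genes among them were low on wild-type replicate 1, at -0.43. Their median was 0.26 with all arrays and 0.14 without that array. The 7 fallen genes, MADS22 included, had a median of -2.65, or -2.28 with MADS3 at its bound. So the tested later genes were not lower, but a younger stage cannot be excluded. The fallen genes were picked because they fell, and the interval treats genes as independent. Of 12 anther wall and tapetum genes with a probe set, only 7 passed the signal filter. A difference in the share of dividing tissue stays open, since the higher DNA replication list lost its call with an estimated correlation (adjusted p = 0.792), had none in fry (adjusted p = 0.542) and was low in wild-type replicate 1. A group difference in RNA quality is argued against by a mean difference of 0.07 in 3' minus 5' log2 signal (-0.07 to 0.2 over the pairs). Under quantile normalization the median of the fallen genes stayed at -2.65. The arrays already had nearly the same mean and similar medians, so that normalization could move it little. It therefore cannot decide whether the authors' scaling plays a part. The difference in genetic background named by the labels stays open and untested, as does an effect of the mutation itself. Each of the fallen genes has only 1 probe set. A sequence difference under the probes therefore cannot be told from lower expression for them.

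LOC4330327 lost nearly all signal in the mutant and directly neighbours MADS6, whose own change was 0.83. Its place was noticed after the values were seen, so chance placement stays open. A lost block that reaches the 20 nearest measured genes is argued against by their median of 0.11, a range of -0.89 to 0.54, and 0 passing over the 20. The closest of these lay at positions -2 and 3 from LOC4330327 in the gene order, so a smaller block is not excluded. A lesion limited to this gene, a sequence difference under its probes, as a block replaced from another background would also bring, and lower expression cannot be separated with the values analysed here, since the gene has 1 probe set. Sequencing the gene in mutant and wild type would tell the first 2 from the third.

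Wild-type replicate 1 had high signal of water stress and abscisic acid genes, of which HOX22, HOX24, PP2C68 and HSF05 were seen first and left out of the added list. Each of these 4 was highest on that array. They were also higher on every wild-type array than on every mutant array, as HOX22 at 738.4 to 1198.3 against 285.2 to 307.1. Between mutant and wild type these 4 passed neither with all arrays, at -1.62, -1.91, -1.37 and -1.57 (limma adjusted p = 0.0786, 0.491, 0.219 and 0.41), nor without that array, at -1.42, -1.45, -1.16 and -1.25 (limma adjusted p = 0.127, 0.256, 0.228 and 0.386, unadjusted 4.75e-05 to 0.000596). On that array the 28 listed genes had a median deviation of 0.75 from the other arrays, at percentile 100 of 10000 random lists matched on signal, and 25 of 28 were higher, while RAB21 read 25028.4 there against 874.2 to 1848.5 on the other arrays. The list was added after such genes had been seen high there. The random lists were not matched on correlation between genes, so the percentile may overstate the support. Stronger RNA degradation on wild-type replicate 1 than on the other arrays is argued against by its 3' minus 5' value of 2.22. The other arrays ran from 1.59 to 3.08, with 2.42 for mutant replicate 1. Degradation common to the arrays was not tested. A stress response in the plants of that sample may be a candidate explanation, and the listed genes had a median of -0.33 between mutant and wild type with all arrays and -0.19 without that array.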
